A study of Homo sapiens with 8 samples.

How the data were processed

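RNA was measured in 8 libraries of MDA-MB-231 cells, grouped by the labels into vehicle dark, vehicle UV-A, 1-SO dark, 1-SO UV-A, 1-S dark and 1-S UV-A. Per the labels' protocols, 600000 cells per well were incubated with compound for 24 h, a plate was irradiated and its partner was kept dark, so that plate and light are the same thing. The time between irradiation and lysis is not given in the sources used here. Messenger RNA was selected with poly-T beads per the labels' protocols. The labels name both a NEB library and a strand-specific library, and whether counting used the strand is not given in the sources used here.

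The authors' deposited tables give read counts per gene as whole numbers, not normalized, with 1 column per library per the file headers. The deposited FPKM values were made by the authors from those counts, the gene length and the library total, which was checked by computing them again. The authors' deposited comparison tables, 9 in number, give a log2 fold change for pairs of libraries per the file headers. The same deposited tables hold the authors' p-values and adjusted p-values, whose adjustment method is not given in the sources used here. The submitters' processing notes name STAR 2.5, HTSeq 0.6.1, TopHat, STAR-Fusion, edgeR 3.16.5 and DESeq2, and the builds hg19 and hg38. The role of each tool, and which build served which round, is not given in the sources used here. Coordinates in the round 2 tables are those of GRCh38 and are the ones printed. The tables of the rounds were made separately, with gene sets and gene lengths that differ, so libraries were only compared within a round. Levels are not comparable between rounds for every gene. Counts of round 1 were taken from the deposited comparison tables and those of round 2 from the deposited count table.

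The rounds shared 45341 gene identifiers, which held 98.15 to 99.23% of the reads of each library, and 27603 of them had at least 1 read. Genes with an FPKM of at least 1 in at least 2 of the 8 libraries were tested, 12696 in all, of which 11256 code for protein. The library totals of 15.8 to 22.6 M reads put the limit that a count of 0 allows (3 reads) at 0.133 to 0.19 CPM. Intervals and limits of this kind cover counting error only, since reads without molecular identifiers are not independent molecules.

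The design was fixed before the data were examined, with limma-trend on log2(FPKM + 1) unless whole counts of both rounds were found. They were found, so the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 was the main test, with TMM factors computed within each round. A single model of the 8 libraries had terms for round, light in vehicle cells and each compound group. It left 1 residual degree of freedom, the difference of the light response of vehicle cells between rounds, and edgeR's moderation added 26 prior degrees of freedom, at a biological coefficient of variation of 12%. The light response of vehicle cells is shared between rounds in this model, although the responses of the rounds correlated at r = -0.111 across genes, so a compound is compared with a fitted vehicle and not with a library of its own round. After the data were examined, called genes were set beside the log2 CPM ratios of the libraries themselves, with each round's own vehicle. In each of the 10 results with calls 0 called genes had the other sign. For UV-A in 1-SO, and for its difference from UV-A in 1-S, the fit compares the same libraries, so the sign could hardly differ. The fitted change was over 1.5 times that of the libraries for 68 of 555 genes of the interaction with 1-SO, for 145 of 2181 and 24 of 451 of the difference between compounds in the dark and under UV-A, and for 18 of 1462 and 44 of 3926 of 1-SO with UV-A and 1-S in the dark against vehicle under the same light. FPKM values quoted beside a fold change are those of the libraries. The test of 1-SO against 1-S was part of the fixed design. The tests of each compound against its vehicle, of UV-A within a compound and of interactions use the same model and were added after the data were examined. The fixed design had no test there and counted genes whose log2(FPKM + 1) differed by at least 1, beside the 38 genes that pass this rule when the difference between the vehicle responses of the rounds, divided by the square root of 2, is put in place of a ratio. That number holds the vehicle response of round 1 and is no measure of noise alone. That scale understates the change of weakly expressed genes. Averages over 4 matched pairs, of light and of compound, had the pair as a block and 3 residual degrees of freedom. P-values were two-sided, adjusted by Benjamini and Hochberg over the genes tested and called at 0.05. In the single model they rest on the spread of the vehicle light response between rounds, moderated across genes. No spread between wells of a compound enters them. In the averages over matched pairs the spread also holds differences of the response between treatments.

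The 32 gene lists were fixed before the data were examined. Of these, 31 had at least 5 measured members, and 16 of their 616 genes stood in more than a single list. For pairs of libraries a list's median log2 ratio was placed among 10000 random lists of equal size matched in 20 bins of mean expression. In the fits, lists were tested with camera at a preset correlation of 0.01 and with fry in limma 3.58.1. With the preset value 9 to 20 lists passed per result. With an estimated correlation camera called 0 lists in each of the results, and the smallest adjusted p of any was 0.497 with an estimated correlation. That estimate rested on the 1 residual degree of freedom of the single model, or 3 for the averages over matched pairs. It could therefore hardly call any list, and a list that failed it is not shown to be unchanged. Counts adjusted over the list alone took the p-values of that list's members only, without correction over lists or results. The fixed design did not name such counts, and they can include genes that fail over all genes tested. Genes were named by a rule fixed in advance, the 8 highest and 8 lowest log2 ratios among protein-coding genes with an FPKM of at least 5 in a library compared, and up to 4 members of each list described with the largest ratios. For light in vehicle cells and for the matched pairs the rule used the mean ratio among genes of a single sign in every pair. Differences between compounds and interactions are given for genes named in the other comparisons.

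The vehicle libraries of the rounds were treated as pairs because the labels assign each to a round. Their deviations from the group means correlated at 0.863, but gene models shared within a round would give this too, so it is no evidence for the pairing. Libraries differed from each other by more than sampling noise in every pair, so none was counted as a repeat. Alternatives fixed in advance were a pseudocount of 0.1, no filter on low values, median-of-ratios scaling, DESeq2 1.42.0, the read counts of round 2, a fit without the block and leaving out each pair. limma-trend on log2(FPKM + 1), TMM over 8 libraries at once, the read counts of round 1 and every alternative of the added tests were chosen after the data were examined. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and statsmodels 0.14.6 served for the pairs of libraries and matplotlib 3.10.9 for the figures.

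Of the tests, 6 were tried on simulated data in which 200 of 12696 genes had a known change and the rounds had the same light response. The tests of either compound with UV-A against vehicle, of UV-A within a compound, of interactions and of 1-SO against 1-S under UV-A were not simulated. Counts were drawn with the same biological coefficient of variation of 12% for every gene and library. That a compound library varies like a vehicle library was thus built in, so the shares of false calls do not test it. For UV-A in vehicle, edgeR recovered 25.4% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 97% of those changed 4-fold, and 4.23% of its calls were false. For 1-SO dark against vehicle dark it recovered 11.9%, 73.1% and 90.9%, with 2.5% false calls. For 1-S dark against vehicle dark it recovered 11.9%, 71.6% and 97%, with 2.44% false calls. For 1-SO against 1-S in the dark the shares were 2.99%, 17.9% and 89.4%, with 2.67% false calls. limma-trend made 4.82 to 25.5% false calls over the simulated comparisons and DESeq2 0 to 4.4%. Of simulated lists of 20 genes with no change 4% lay outside the central 95% of random lists, and with a shift of 0.5 on the log2 scale 100% did. The genes of these lists were simulated as independent. These shares, and a place among random lists, therefore take no account of members that move together.

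Reads of near-identical genes, such as HSPA1A and HSPA1B, histone genes, and mitochondrial genes with their nuclear copies, can be split in ways that depend on the counting, and the values of such genes and of overlapping or antisense genes are uncertain. Genes listed in a single round were left out of the tests.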

Results

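Gene expression was measured by sequencing of poly-A-selected RNA from MDA-MB-231, an established human line of triple-negative breast cancer cells. The cells had received 1 of 2 related triphenylphosphonium salts or the solvent, and were then irradiated with UV-A or kept dark. 1-SO is (5-oxo-2-dibenzothienylmethyl)triphenylphosphonium, and 1-S, (2-dibenzothienylmethyl)triphenylphosphonium, lacks that oxo group. Triphenylphosphonium is a lipophilic cation widely used to carry molecules into mitochondria. Each compound was given at 10 µM for 24 h and the vehicle was 1% DMSO. UV-A exposure lasted 30 min under 8 bulbs that emit between 325 and 375 nm.

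The 8 libraries fell into 6 groups. Vehicle dark and vehicle UV-A had n = 2 libraries each, 1 from each of 2 rounds, while 1-SO dark, 1-SO UV-A, 1-S dark and 1-S UV-A had n = 1 library each. Round 1 held the 1-SO wells, with cells at passage 8, and round 2 the 1-S wells, with cells at passage 32 to 34. In round 1 the vehicle dark library had 18.8 M counted reads and the vehicle UV-A library 15.8 M. The 1-SO dark library had 17.8 M and the 1-SO UV-A library 22.2 M. In round 2 the totals were 22.6 M for vehicle dark, 21.8 M for vehicle UV-A, 21.8 M for 1-S dark and 19.1 M for 1-S UV-A. No compound group has a replicate check. Tests of compound effects took their spread from the vehicle libraries, with the assumption that a single compound library varies like a vehicle library. Compound, round and passage changed together, so compound and batch cannot be told apart. The fit shares the light response of vehicle cells between rounds, and where a change differs by much from that against a round's own vehicle library, the latter is given too.

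Vehicle cells were compared first, to see what UV-A did without compound. The response differed between the rounds. In round 1, mRNA for the xenobiotic-metabolising enzyme CYP1A1 was at 1.76 FPKM (fragments per kilobase of gene and 1 M reads) in the dark and 8.15 after UV-A, and in round 2 at 2.26 and 2.37. The collagenase MMP1 went from 24.7 to 141 FPKM in round 1, against 12 and 10.8 in round 2. The early-response transcription factor FOS was higher in both rounds, at 3.01 and 7.97 FPKM and then at 3.52 and 4.98, and the hair keratin KRT81 was lower in both, at 59.4 and 17.4 and then at 35.0 and 25.5. None of these passed the test over both rounds. Over the 2 rounds the log2 fold change was 1.09 ± 0.32 (SE) for CYP1A1, with an edgeR adjusted p of 0.7, and 0.90 ± 0.18 for FOS, with an edgeR adjusted p of 0.11. For KRT81 it was -1.13 ± 0.20 and the edgeR adjusted p was 0.062. CST1, a secreted cystatin, had the same edgeR adjusted p of 0.062 at -0.74 ± 0.14.

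Gene lists moved apart in the same way. The 25 DNA replication genes had a median log2 ratio of -0.65 in round 1, below all 10000 random lists of matched expression, and of 0.10 in round 2. Medians in rounds 1 and 2 were 0.87 and -0.02 for the 8 aryl hydrocarbon receptor targets, 0.44 and -0.01 for the 23 NRF2 targets, and -0.40 and 0.04 for the 52 cytosolic ribosomal protein genes. The 28 G2/M genes of mitosis were higher in both rounds, with medians of 0.40 and 0.14, each above all 10000 random lists. With p adjusted over the list alone, 7 of the 28 G2/M genes passed as higher in the fit over both rounds. So did 4 of the 8 aryl hydrocarbon receptor targets and 3 of the 23 NRF2 targets, while 4 of the 18 extracellular matrix genes passed as lower. This adjustment is laxer than that over all genes, where no gene passed. The round 2 medians of the aryl hydrocarbon receptor and NRF2 lists, given above, showed no rise. In camera each of these lists had an adjusted p = 0.776 with an estimated correlation. The numbers of genes that differed at least 2-fold were 76 in round 1 and 25 in round 2. Across genes, which are not independent replicates, the log2 ratios of the rounds correlated at r = -0.111. In the test over both rounds edgeR called 0 of 12696 genes, with 347 at an unadjusted p under 0.05. DESeq2 called 0 as well, with 73, and limma-trend called 7. The authors' deposited table for round 1 listed 3 genes as higher and 5 as lower at an adjusted p under 0.05, and the authors' deposited table for round 2 listed 0.

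1-SO in the dark was compared with vehicle in the dark to see what the sulfoxide did without light. No gene passed the test and the libraries were close. ANAPC10, a subunit of the anaphase-promoting complex, had the highest ratio, at 12.8 FPKM against 7.42, and the neuropeptide gene NMU the lowest, at 7.24 against 10.4. Their log2 fold changes were 0.66 ± 0.34 and -0.64 ± 0.36 (SE), each with an edgeR adjusted p of 1. The cyclin gene CCNE1 was also among the 8 lowest. By size 20 genes differed at least 2-fold, 9 higher and 11 lower, beside 38 for the difference between the vehicle responses of the rounds. The 13 mitochondrially encoded mRNAs had a median log2 ratio of 0.24, above all 10000 random lists. For this list camera gave an adjusted p = 0.932 with an estimated correlation, but that test could hardly call any list. The 27 genes of the ATF4 integrated stress response had a median of 0.01. edgeR called 0 genes, with 26 at an unadjusted p under 0.05, DESeq2 called 0 and limma-trend called 2. In the authors' deposited table no gene passed, and the smallest adjusted p there was 1.

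**Figure D1:**
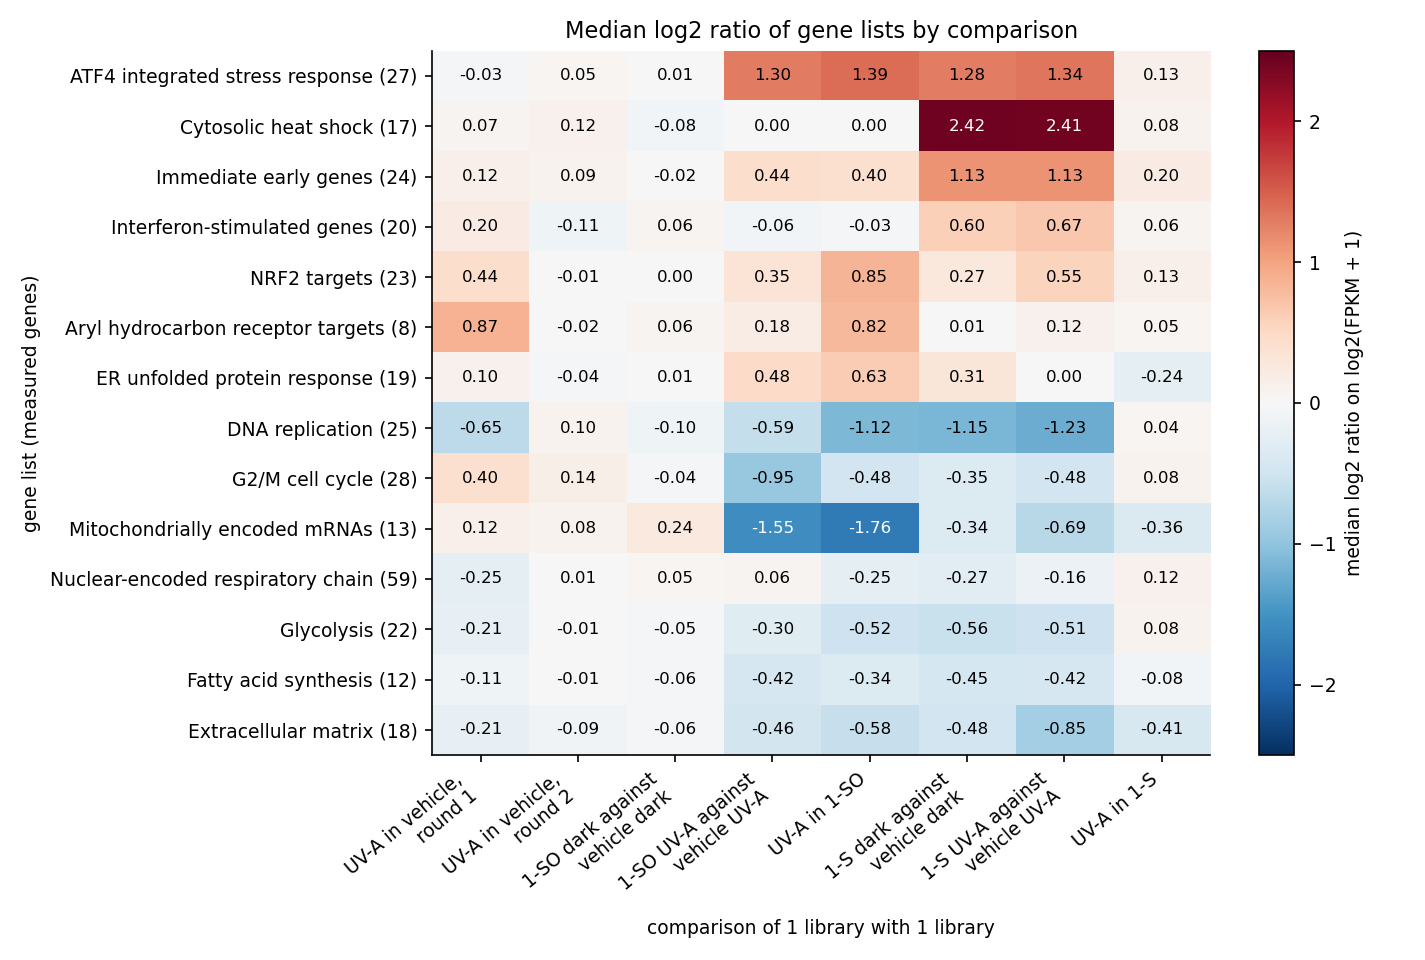
Median log2 ratio of FPKM + 1 for 14 gene lists, listed down the side with the number of genes measured, in 8 comparisons of 1 library with 1 library. Red is higher and blue lower than the library compared with; the cytosolic heat shock list stands at 2.42 and 2.41 in the 1-S comparisons and at 0.00 for 1-SO with UV-A, while the mitochondrially encoded mRNAs reach -1.55 for 1-SO with UV-A.

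1-SO together with UV-A was compared with vehicle UV-A, the effect of the sulfoxide in irradiated cells. Genes of the integrated stress response rose, while mitochondrially encoded mRNAs and genes of mitosis and DNA replication fell. GDF15, a stress-induced cytokine (ENSG00000130513, GRCh38 chromosome 19, 18374731 to 18389176), rose from 4.23 to 32.9 FPKM, a log2 fold change of 2.79 ± 0.20 (SE, edgeR adjusted p = 6.6e-10). TRIB3, a pseudokinase induced by ATF4, rose from 22.4 to 122 FPKM (2.38 ± 0.18, edgeR adjusted p = 7.8e-10), and DDIT4, an inhibitor of mTORC1, from 15.5 to 89.1 (2.38 ± 0.18). DDIT3, which encodes the transcription factor CHOP, rose from 5.16 to 23.7 FPKM (2.21 ± 0.25). CTH, which makes cysteine, rose from 14.4 to 68.9 FPKM (2.36 ± 0.21), and CHAC1, which degrades glutathione, from 12 to 48.0 (1.97 ± 0.21). ADM2 and NUPR1 rose by log2 2.85 ± 0.25 and 2.69 ± 0.29. Of the 27 measured genes of the ATF4 list, 24 rose and 0 fell, or 25 and 0 when adjusted over the list alone. The list's median log2 ratio of 1.30 lay above all 10000 random lists, and its adjusted p = 0.725 with an estimated correlation.

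The mitochondrially encoded mRNAs, which specify subunits of the respiratory chain and ATP synthase, fell in 12 of 13 cases, or in all 13 when adjusted over the list alone. Their median log2 ratio was -1.55, below all 10000 random lists (adjusted p = 0.725 with an estimated correlation). MT-ND6 (ENSG00000198695, mitochondrial genome 14149 to 14673, minus strand) went from 513 to 55.1 FPKM, a log2 fold change of -3.34 ± 0.21 (SE, edgeR adjusted p = 3.4e-11). It lies antisense to a longer transcript, and whether counting used the strand is not given in the sources used here. MT-ND3 went from 1568 to 367 FPKM (-2.33 ± 0.24), MT-CYB from 1098 to 283 (-2.08 ± 0.25) and MT-CO2 from 4610 to 1163 (-2.07 ± 0.30). Mitochondrial genes took 0.93% of the reads of this library, against 2.76% in vehicle UV-A and 3.02% in 1-SO dark. The 59 nuclear-encoded respiratory chain genes had a median log2 ratio of 0.06 on FPKM and of -0.12 in the edgeR fit, and 0 of them passed. With UV-A in 1-SO, however, the fitted median was -0.40 and 4 fell, also when adjusted over the list alone (adjusted p = 0.729 with an estimated correlation). Against vehicle dark it was -0.28, with 1 that rose and 1 that fell, or 0 and 0 when adjusted over the list alone (adjusted p = 0.861 with an estimated correlation). Light alone had a median log2 ratio of -0.25 in the vehicle cells of round 1, with 53 of 59 below 0.

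**Figure D2:**
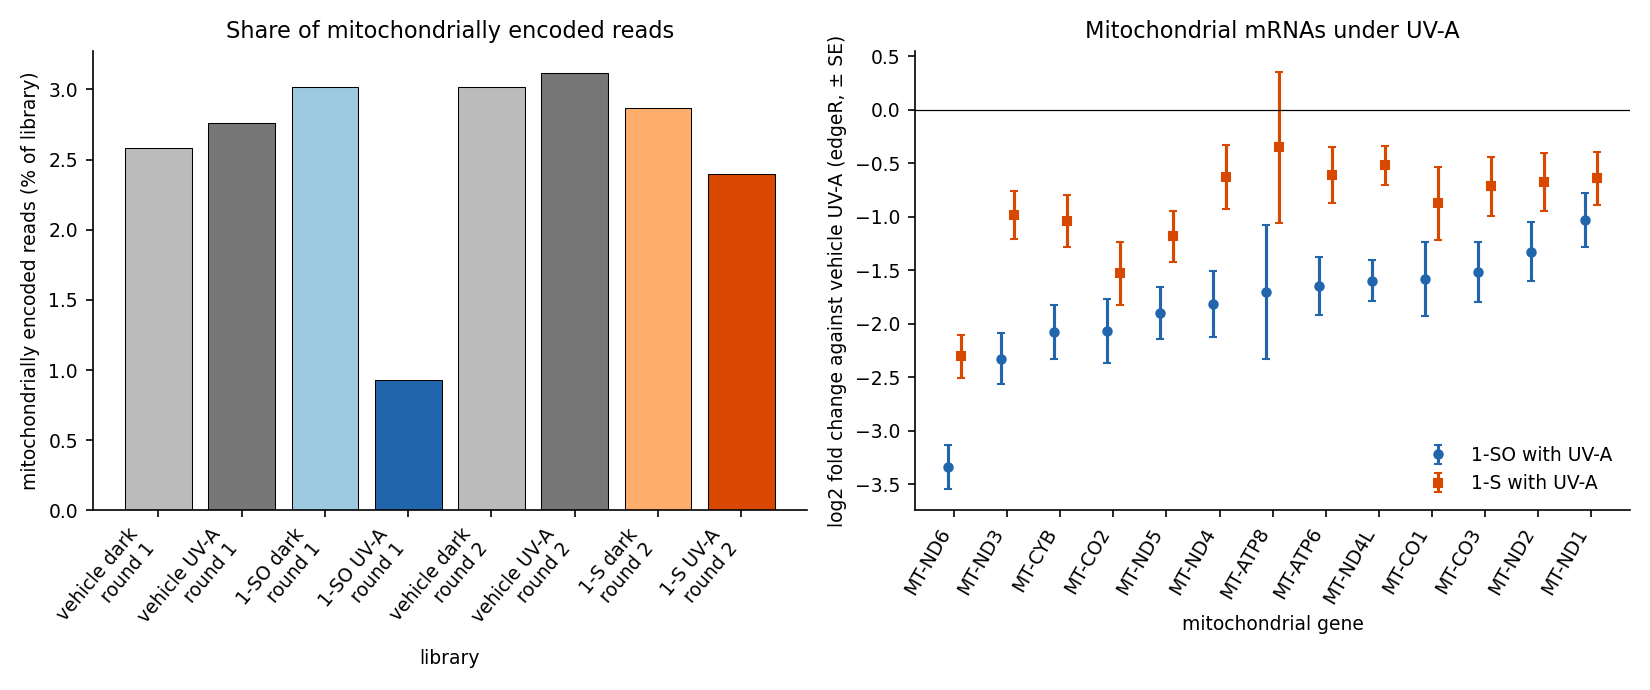
Left, mitochondrially encoded reads as a percentage of all counted reads in each of the 8 libraries, as bars from 0. Right, log2 fold change against vehicle UV-A of the 13 mitochondrially encoded mRNAs for 1-SO and for 1-S with UV-A, as points with bars of 1 standard error from the edgeR fit; the 1-SO UV-A library stands at 0.93% on the left, and its 13 points lie below 0 on the right.

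Genes of cell division fell together. In the G2/M list 25 of 28 genes fell and 0 rose, or 28 and 0 when adjusted over the list alone (adjusted p = 0.725 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell from 115 to 39.1 FPKM, a log2 change of -1.64 ± 0.19. PLK1, a mitotic kinase, changed by -1.71 ± 0.20 and the spindle motor KIF20A by -1.87 ± 0.22, with edgeR adjusted p values of 1.8e-06 and 2.1e-06. Part of this lies in the comparator, as KIF20A stood at 22.9 FPKM in vehicle dark, 48.2 in vehicle UV-A and 12.2 in 1-SO with UV-A, and PLK1 at 14.8, 24.5 and 7.61. Against vehicle dark the G2/M list had a fitted median of -0.73 and 20 of 28 fell, or 25 when adjusted over the list alone (adjusted p = 0.677 with an estimated correlation). For UV-A in 1-SO the median was -0.64 and 17 fell, or 23 when adjusted over the list alone (adjusted p = 0.729 with an estimated correlation). In the DNA replication list 20 of 25 fell, or 24 when adjusted over the list alone (adjusted p = 0.725 with an estimated correlation), among them the transcription factor E2F1 (-1.56 ± 0.25), the helicase component GINS2 (-1.79 ± 0.33) and thymidylate synthase, TYMS (-1.66 ± 0.26). The median of that list was -0.97 in the fit and -0.71 against the vehicle UV-A library of round 1. Of 22 glycolysis genes, 6 fell and 1 rose, or 10 and 1 when adjusted over the list alone (adjusted p = 0.747 with an estimated correlation). Lactate dehydrogenase A, LDHA, fell from 344 to 163 FPKM, whereas the glucose transporter SLC2A3 rose by log2 1.35.

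Some genes of other stress responses rose. Of 23 NRF2 targets 9 rose and 0 fell, the same when adjusted over the list alone (adjusted p = 0.747 with an estimated correlation). They included haem oxygenase HMOX1, from 8.92 to 28.3 FPKM (log2 1.59 ± 0.20), the cystine transporter SLC7A11, from 21 to 67.5 (1.89 ± 0.24), and the ferritin heavy chain FTH1, from 207 to 488 (1.31 ± 0.20). In the list of the endoplasmic reticulum unfolded protein response 7 of 19 rose, or 9 when adjusted over the list alone (adjusted p = 0.725 with an estimated correlation), including XBP1 (1.21 ± 0.18) and the stress sensor ERN1 (1.54 ± 0.21). Of 19 p53 targets 5 rose and 0 fell, also when adjusted over the list alone, and the fry test of movement in 1 direction gave an adjusted p of 0.0109 for this list, which camera left at an adjusted p = 0.725 with an estimated correlation. The cell cycle inhibitor CDKN1A rose from 81.4 to 250.0 FPKM (1.54 ± 0.19, edgeR adjusted p = 5.1e-06). Of 24 immediate early genes 10 rose and 2 fell, or 11 and 2 when adjusted over the list alone (adjusted p = 0.725 with an estimated correlation), with KLF4 at 1.01 ± 0.18 and JUNB at 1.02 ± 0.17. In the cytosolic heat shock list 1 of 17 genes rose, or 2 with 1 that fell when adjusted over the list alone, and the adjusted p = 0.802 with an estimated correlation. The list's fitted log2 changes had a median of -0.31 and a mean of 0.05, but against the vehicle UV-A library of round 1 the median was -0.02, with 8 genes above and 9 below 0. HSPA6 was the gene that rose, from 1.05 to 4.47 FPKM (2.46 ± 0.35, edgeR adjusted p = 3.1e-05).

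Matrix genes moved both ways. MMP1 (ENSG00000196611, chromosome 11, 102789920 to 102798160) rose from 141 to 387 FPKM, a log2 change of 1.86 ± 0.33 (SE, edgeR adjusted p = 0.0004), while its list mates PLAU, which activates plasminogen, and the protease inhibitor TIMP3 each fell by 1.70 on the log2 scale. Of 18 extracellular matrix genes 10 fell and 0 rose, or 11 and 0 when adjusted over the list alone (adjusted p = 0.725 with an estimated correlation), with the collagen gene COL13A1 at -1.54 ± 0.21. The organic anion transporter SLCO4A1 went from 29.5 to 4.92 FPKM (-2.72 ± 0.20, edgeR adjusted p = 7.8e-10) and the adhesion protein gene TNS4 from 5.29 to 0.476 (-3.49 ± 0.40). In all, edgeR called 1462 of 12696 genes, 567 higher and 895 lower. limma-trend on log2(FPKM + 1) divided its calls as 777 higher and 597 lower, and DESeq2 called 471 genes. By size alone 344 genes differed at least 2-fold, 185 higher and 159 lower. The authors' deposited table listed 25 genes higher and 37 lower at an adjusted p under 0.05.

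UV-A in cells that held 1-SO was compared with 1-SO kept dark, the effect of light on treated cells. MMP1 rose from 25.4 to 387 FPKM, a log2 change of 3.81 ± 0.43 (SE, edgeR adjusted p = 8.5e-07), and SLC7A11 by 2.67 ± 0.28. CYP1B1, which oxidises polycyclic compounds, rose from 7.53 to 45.5 FPKM (2.47 ± 0.38), and PPP1R15A, the regulatory subunit that restores eIF2 after stress, from 72.1 to 356 (2.18 ± 0.25). LFNG, a glycosyltransferase that modifies Notch (ENSG00000106003, chromosome 7, 2512529 to 2529177), went from 11.5 to 0.644 FPKM (-4.27 ± 0.41, edgeR adjusted p = 8e-08). IGFBP4, a binding protein of insulin-like growth factors, went from 1277 to 257 FPKM (-2.44 ± 0.30), and MT-ND6 from 614 to 55.1. The ATF4 list had 24 of 27 genes higher, or 25 when adjusted over the list alone, with asparagine synthetase ASNS at 2.04 ± 0.20. The DNA replication list had 23 of 25 lower, or 25 when adjusted over the list alone, the NRF2 list 12 of 23 higher, or 13, and the mitochondrially encoded list 12 of 13 lower, the same number in both adjustments. Of 8 aryl hydrocarbon receptor targets 3 rose and 1 fell, or 5 and 1 when adjusted over the list alone. Each of these lists had an adjusted p = 0.729 with an estimated correlation. In the vehicle cells of round 1 UV-A had also raised the medians of the NRF2 and aryl hydrocarbon receptor lists and lowered that of DNA replication. The direction of these changes is therefore not particular to cells with 1-SO. The median fitted interaction of UV-A with 1-SO was -1.03 for DNA replication, 0.55 for NRF2 targets and 0.36 for aryl hydrocarbon receptor targets. Typical members had 95% intervals of ± 0.6, ± 0.57 and ± 0.76. Against the vehicle UV-A library of round 1, 1-SO with UV-A had 25 of 25 DNA replication genes below 0. There 16 of 23 NRF2 targets and 4 of 8 aryl hydrocarbon receptor targets lay above 0.

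edgeR called 1877 genes for UV-A in 1-SO, 708 higher and 1169 lower, and limma-trend on log2(FPKM + 1) 1092 higher and 795 lower. DESeq2 called 585. By size 647 genes differed at least 2-fold, 336 higher and 311 lower. Against vehicle dark, the library of 1-SO with UV-A differed in 2041 genes by edgeR, 794 higher and 1247 lower, in 1248 higher and 841 lower by limma-trend, and in 685 by DESeq2. There the size rule gave 710 genes. Median-of-ratios scaling moved the median log2 ratio of all genes by -0.107 for UV-A in 1-SO and by -0.127 for 1-SO with UV-A against vehicle dark, which leaves the changes above well outside that shift. The authors' deposited table for 1-SO with UV-A against vehicle dark listed 145 genes higher and 261 lower at an adjusted p under 0.05.

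Whether UV-A acted differently with 1-SO than with vehicle was tested as an interaction. Most mitochondrially encoded mRNAs and ATF4 genes showed such a difference. The interaction was -3.62 ± 0.25 (log2, SE) for MT-ND6, with an edgeR adjusted p of 3.29e-10, -2.71 ± 0.29 for MT-ND3 and -2.28 ± 0.37 for MT-CO2. It was 2.68 ± 0.27 for GDF15, with an edgeR adjusted p of 9.12e-07, 2.28 ± 0.24 for TRIB3 and 2.52 ± 0.29 for CTH. For MMP1 it was 2.59 ± 0.50, but 1.36 with the vehicle libraries of round 1 alone, where MMP1 was higher with light in vehicle cells too. Of the 13 mitochondrially encoded mRNAs 12 passed, all lower and the same number when adjusted over the list alone. Of the 27 ATF4 genes 21 passed as higher, or 24 when adjusted over the list alone, and of the 28 G2/M genes 16 as lower, or 24. Each list had an adjusted p = 0.694 with an estimated correlation. Over all genes 555 passed in edgeR, 187 with a more positive and 368 with a more negative response, against 229 and 202 by limma-trend on log2(FPKM + 1) and 146 in all by DESeq2.

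1-S in the dark was compared with vehicle in the dark, the effect of the compound without the oxo group and without light. Heat shock genes rose together. HSPA6, an inducible HSP70 (ENSG00000173110, chromosome 1, 161524540 to 161526910), rose from 1.2 to 987 FPKM, a log2 change of 9.99 ± 0.35 (SE, edgeR adjusted p = 9.7e-18). HSPA1A rose from 8.39 to 810.1 FPKM (6.58 ± 0.23) and HSPA1B from 30.5 to 2223 (6.12 ± 0.27); these are near-identical genes on chromosome 6 whose reads counting could split either way. DNAJB1, the HSP40 partner of HSP70, rose from 88.9 to 2646 FPKM (4.78 ± 0.30, edgeR adjusted p = 2.1e-12). Of the 17 measured genes of the cytosolic heat shock list 16 rose and 0 fell, or 17 when adjusted over the list alone. The list's median log2 ratio of 2.42 lay above all 10000 random lists, and its adjusted p = 0.663 with an estimated correlation. The 10 most abundant genes took 7.04% of the reads in this library and 4.66% in its vehicle.

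The integrated stress response and early-response genes rose with them. GDF15 rose from 6.03 to 125 FPKM (4.26 ± 0.20, edgeR adjusted p = 5.2e-15), DDIT3 from 4.48 to 52.2 (3.58 ± 0.25), PPP1R15A from 54.2 to 546 (3.35 ± 0.22) and TRIB3 from 13.51 to 109.9 (2.99 ± 0.18). Of the 27 ATF4 genes 21 rose and 1 fell, or 23 and 1 when adjusted over the list alone, and fry gave an adjusted p of 0.034 for movement in 1 direction (adjusted p = 0.663 with an estimated correlation in camera). FOS rose from 3.52 to 77.1 FPKM (4.6 ± 0.21) and the phosphatase gene DUSP1 by log2 3.03, and 16 of 24 immediate early genes rose and 2 fell, the same when adjusted over the list alone (adjusted p = 0.663 with an estimated correlation). SNAI1, a repressor of epithelial genes, rose from 0.158 to 26.0 FPKM (7.27 ± 0.39), from 6 reads in the vehicle library. GADD45G, a growth arrest gene, rose from 0.235 to 32.0 FPKM (7.06 ± 0.41) and RGS2, which limits G protein signalling, from 1.92 to 51.0 (4.80 ± 0.24). Of 23 NRF2 targets 9 rose and 2 fell, the same when adjusted over the list alone (adjusted p = 0.695 with an estimated correlation), and HMOX1 rose from 5.14 to 50.2 FPKM (3.25 ± 0.20).

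Some interferon-stimulated and unfolded protein response genes rose too. IFIT2, an antiviral RNA-binding protein gene, rose from 16.8 to 193 FPKM (3.46 ± 0.19, edgeR adjusted p = 9.6e-14), OASL from 1.73 to 23.4 (3.55 ± 0.28) and IFIT1 from 7.43 to 63.9 (log2 3.19). Of 20 interferon-stimulated genes 11 rose and 1 fell, the same when adjusted over the list alone, with a median log2 ratio of 0.60 at percentile 99.99 of random lists (adjusted p = 0.663 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, rose from 332 to 1716 FPKM (2.32 ± 0.27) and HERPUD1, which serves degradation of its proteins, from 16.6 to 76.6 (2.16 ± 0.18). In that unfolded protein response list 6 of 19 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.663 with an estimated correlation).

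Most genes of the replication, glycolysis and matrix lists fell after 1-S in the dark. Of 25 DNA replication genes 24 fell and 0 rose, also when adjusted over the list alone, with a median log2 ratio of -1.15 below all 10000 random lists (adjusted p = 0.663 with an estimated correlation). E2F1 fell from 62.2 to 13.9 FPKM (-2.51 ± 0.26), the helicase gene MCM6 from 30.6 to 8.43 (-2.19 ± 0.25) and the ribonucleotide reductase gene RRM2 from 27.7 to 6.63 (-2.32 ± 0.23). In the G2/M list 9 of 28 fell, the same when adjusted over the list alone (adjusted p = 0.663 with an estimated correlation). Of 22 glycolysis genes 13 fell and 1 rose, in both adjustments (adjusted p = 0.695 with an estimated correlation), LDHA falling from 230 to 84.2 FPKM and SLC2A3 rising by log2 1.95. Of 18 extracellular matrix genes 11 fell and 2 rose, or 12 and 2 when adjusted over the list alone (adjusted p = 0.663 with an estimated correlation). COL13A1 changed by -1.85 on the log2 scale, and COL1A1 was 1 of the genes that rose, from 1.45 to 7.09 FPKM (2.34 ± 0.23). Of 13 mitochondrially encoded mRNAs 4 fell, also when adjusted over the list alone (adjusted p = 0.663 with an estimated correlation), with MT-ND6 at -1.86 ± 0.19. The 59 nuclear-encoded respiratory chain genes had a fitted median of -0.42, and 54 lay below 0 against the vehicle dark library of round 2. With 1-S and UV-A their fitted median was -0.14, and 52 lay below 0 against the vehicle UV-A library of round 2. SLCO4A1 (ENSG00000101187, chromosome 20, 62642445 to 62685785) fell from 59.3 to 4.88 FPKM (-3.70 ± 0.21, edgeR adjusted p = 3.4e-13) and IGFBP4 from 1678 to 253 (-2.87 ± 0.30).

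edgeR called 3926 genes for 1-S in the dark, 2024 higher and 1902 lower. The balance depended on the method, with 727 higher and 842 lower of the 1569 that DESeq2 called, 1947 and 1439 by limma-trend on log2(FPKM + 1), and 1842 and 2199 in edgeR with no filter on low values. By size 837 genes differed at least 2-fold, 545 higher and 292 lower. The authors' deposited table listed 603 genes higher and 247 lower at an adjusted p under 0.05.

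**Figure D3:**
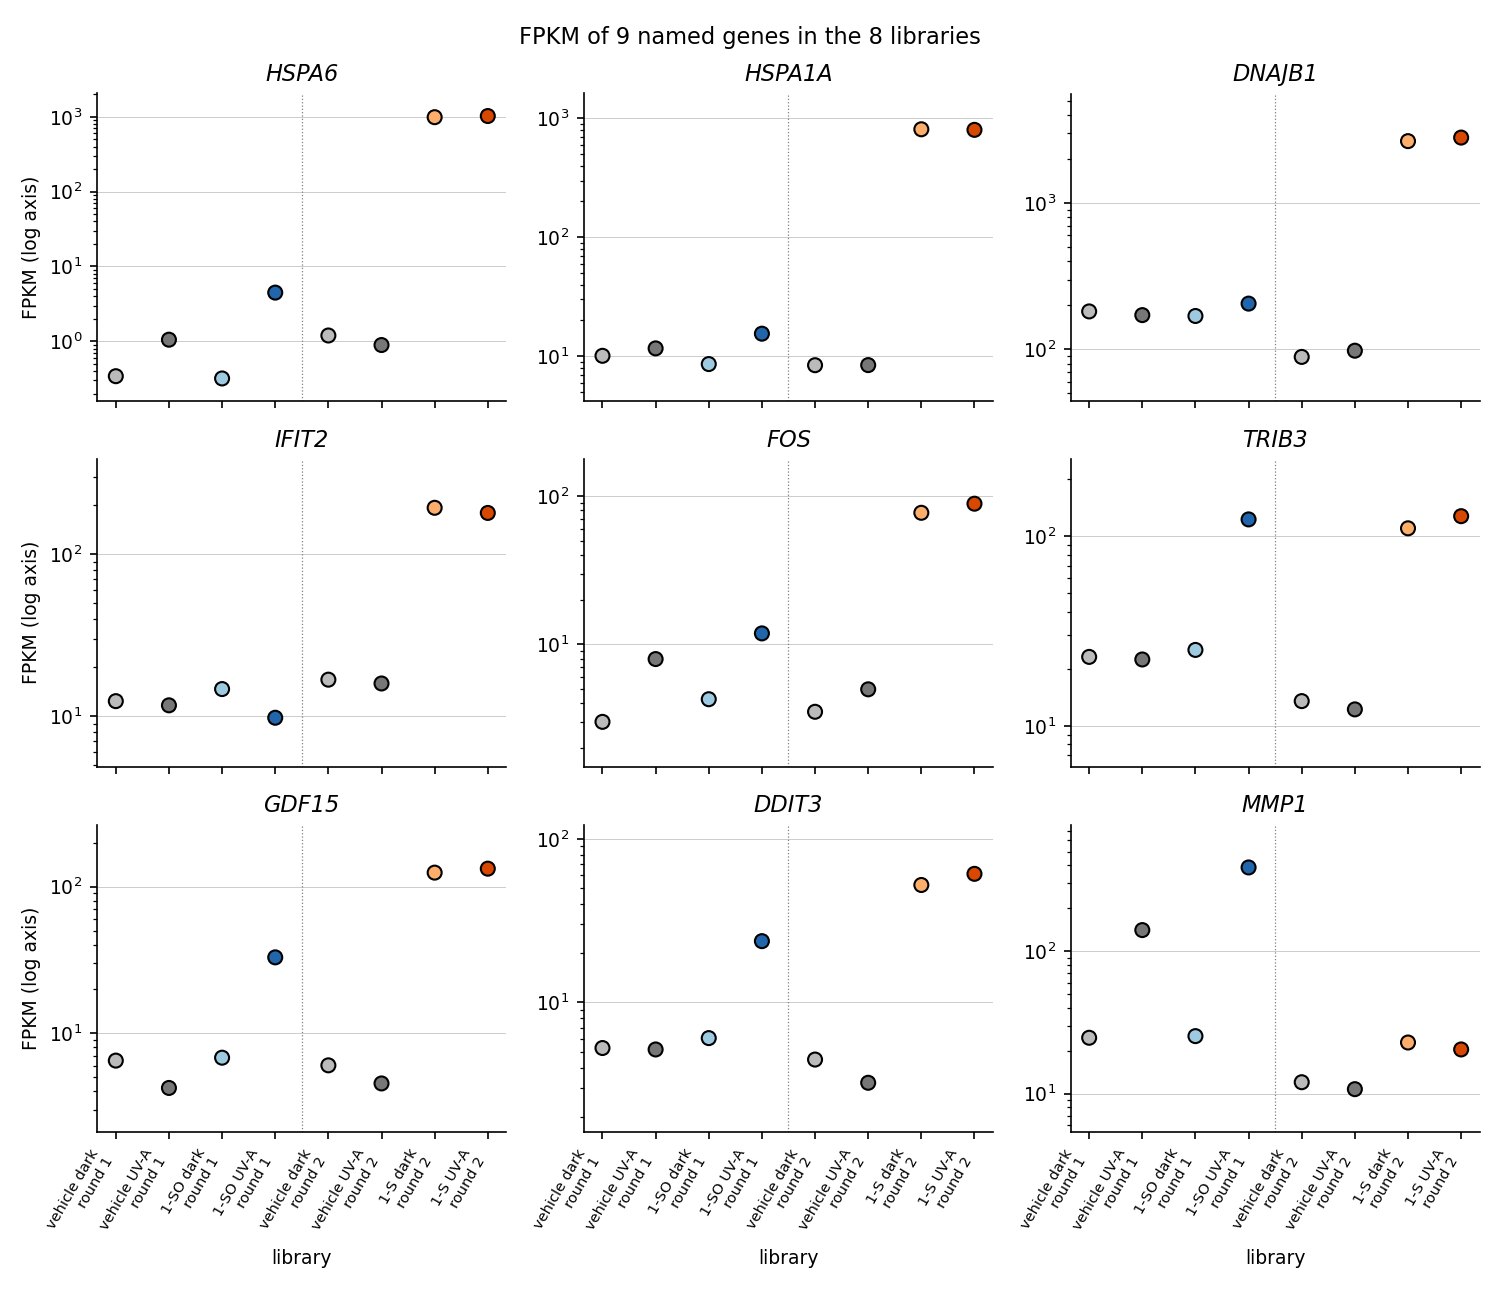
FPKM on log axes of 9 genes in the 8 libraries, 1 point per library, with round 1 left and round 2 right of the dotted line. Within round 2 HSPA6 stands at 1.2 FPKM in vehicle dark and at 987 in 1-S dark, and within round 1 TRIB3 stands at 22.4 in vehicle UV-A and at 122 in 1-SO with UV-A.

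1-S with UV-A was compared with vehicle UV-A. The heat shock genes and most ATF4 genes rose here too. The log2 fold changes were 9.69 ± 0.38 (SE) for HSPA6, with an edgeR adjusted p of 1.6e-16, 6.48 for HSPA1A, 4.84 ± 0.29 for DNAJB1 and 4.87 ± 0.20 for GDF15. ARC, an activity-regulated immediate early gene, rose from 2.11 to 63.3 FPKM (4.42 ± 0.27, edgeR adjusted p = 1.2e-12). All 17 heat shock genes and 23 of 27 ATF4 genes rose, the same when adjusted over the list alone, and 17 of 24 immediate early genes rose with 2 that fell in both adjustments. Of 20 interferon-stimulated genes 9 rose and 1 fell, or 11 and 1 when adjusted over the list alone. Of 28 G2/M genes 15 fell, or 20, of 18 extracellular matrix genes 13 fell and 1 rose, or 14 and 1, and of 13 mitochondrially encoded mRNAs 6 fell, or 12, the second count of each being adjusted over the list alone. Each of these lists had an adjusted p = 0.619 with an estimated correlation. Of 25 DNA replication genes 21 fell, also when adjusted over the list alone (adjusted p = 0.736 with an estimated correlation). Of the 19 genes of the unfolded protein response 6 rose and 0 fell, or 6 and 2 when adjusted over the list alone, and the fitted median was -0.10 (adjusted p = 0.836 with an estimated correlation). MT-ND6 fell from 345 to 71.0 FPKM (-2.31 ± 0.20, edgeR adjusted p = 1.2e-09). The membrane protein gene HEG1 changed by -2.46 ± 0.22 and the guidance receptor gene PLXNA1 by -2.51 ± 0.22.

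edgeR called 3488 genes for 1-S with UV-A against vehicle UV-A, 1746 higher and 1742 lower, and 3916 against vehicle dark, 1961 higher and 1955 lower. DESeq2 called 1463, 634 higher and 829 lower, and 1716, 728 higher and 988 lower, whereas limma-trend on log2(FPKM + 1) had 1673 higher and 1402 lower, and 1927 and 1510. By size 1017 and 930 genes differed at least 2-fold. The authors' deposited table listed 574 genes higher and 312 lower against vehicle UV-A, and the authors' deposited table against vehicle dark 530 and 336. Across genes, the ratios of 1-S to vehicle in the dark and under UV-A, which share no library, correlated at r = 0.902. Of the genes at least 2-fold higher, 423 were shared between these comparisons, against 27.0 if they were unrelated, and of those at least 2-fold lower 215, against 8.9.

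UV-A in cells that held 1-S, compared with 1-S kept dark, changed no gene past the test. COL12A1, a collagen gene among the 8 lowest, was at 9.67 FPKM in the dark and 4.84 after UV-A (log2 -1.01 ± 0.19 SE, edgeR adjusted p = 0.11). FAT1, an atypical cadherin gene, was at 24.2 and 12 FPKM (-1.02 ± 0.24, edgeR adjusted p = 0.48). The histone gene HIST1H1C was among the highest, at 0.70 ± 0.22. All 18 extracellular matrix genes had ratios below 0, with a median log2 of -0.41 below all 10000 random lists, and 9 of them passed when adjusted over the list alone against 0 over all genes (adjusted p = 0.831 with an estimated correlation). The mitochondrially encoded mRNAs had a median of -0.36, also below all 10000 random lists (adjusted p = 0.831 with an estimated correlation). edgeR called 0 genes, with 307 at an unadjusted p under 0.05, DESeq2 0 with 72, and limma-trend on log2(FPKM + 1) 0. The interaction of UV-A with 1-S gave 0 genes in edgeR, with 285 at an unadjusted p under 0.05, 0 in DESeq2 and 6 in limma-trend. By size 42 genes differed at least 2-fold, beside 38 for the difference between the vehicle responses of the rounds. The table deposited by the authors listed 0 genes, its smallest adjusted p being 0.554.

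The compounds, which differ in structure by the oxo group, were then compared at the matched dose and time. Each was taken relative to vehicle in the fit over both rounds. Round and passage differed between the compounds as well, so a difference in response cannot be assigned to the oxo group. In the dark the responses differed widely. The response to 1-SO minus that to 1-S was -10.86 ± 0.58 (log2, SE) for HSPA6, with an edgeR adjusted p of 4.09e-13, -4.82 ± 0.40 for DNAJB1, -4.15 ± 0.28 for GDF15, -2.89 ± 0.24 for TRIB3 and -3.21 ± 0.25 for IFIT2. It was 2.62 ± 0.31 for E2F1, with an edgeR adjusted p of 9.25e-07, and 2.13 ± 0.24 for MT-ND6. Of 17 heat shock genes 15 were less responsive to 1-SO than to 1-S, or 16 when adjusted over the list alone. Of 27 ATF4 genes 18 were lower, or 20 with 1 higher, and of 20 interferon-stimulated genes 10 were lower and 1 higher in both adjustments. Of 25 DNA replication genes 23 were higher, or 24, and of 22 glycolysis genes 10 were higher and 1 lower, or 13 and 1, again with the second count adjusted over the list alone. The median difference of the DNA replication list was 1.65 in the fit and 1.13 with the vehicle library of each round. The heat shock, ATF4, interferon-stimulated, DNA replication and glycolysis lists each had an adjusted p = 0.7 with an estimated correlation. For the 13 mitochondrially encoded mRNAs the median difference was 0.69 in the fit, with a typical 95% interval of ± 0.7. MT-ND6, at 2.13, therefore does not stand for that list. edgeR called 2181 genes, 1067 with a more positive and 1114 with a more negative response to 1-SO, and with no filter on low values 1280 and 963. DESeq2 called 634, 329 and 305, and limma-trend on log2(FPKM + 1) 753 and 1014.

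Under UV-A the difference between the compounds varied by group. The heat shock genes still set them apart, as the difference was -7.22 ± 0.49 (log2, SE) for HSPA6, with an edgeR adjusted p of 6.26e-11, and 17 of 17 genes of the list were lower with 1-SO, the same when adjusted over the list alone. Of 20 interferon-stimulated genes 9 were lower, or 10 when adjusted over the list alone, with IFIT2 at -3.81. Of 24 immediate early genes 12 were lower in both adjustments. For the ATF4 list the median difference was -0.09, and a typical member had a 95% interval of ± 0.54. Of its 27 genes 7 were lower and 1 higher with 1-SO, or 9 and 3 when adjusted over the list alone. TRIB3 differed by -0.94 ± 0.24, with an edgeR adjusted p of 0.023, and GDF15 by -2.08 ± 0.26, whereas DDIT4 differed by 0.09 ± 0.24, with an edgeR adjusted p of 0.932. DNA replication genes had a median difference of 0.15 in the fit, with a typical 95% interval of ± 0.61, but of 0.70 with the vehicle UV-A library of each round, where 23 of 25 had a positive difference. In the fit 1 of 25 was higher, or 1 higher and 1 lower when adjusted over the list alone. These lists had an adjusted p = 0.858 with an estimated correlation, except DNA replication at an adjusted p = 0.946 with an estimated correlation.

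Some genes passed as more responsive to 1-SO than to 1-S under UV-A, by an amount that depended on the vehicle. MMP1 differed by 1.80 ± 0.50 (log2, SE), with an edgeR adjusted p of 0.0392, CYP1B1 by 1.90 ± 0.46 and SLC7A11 by 1.2 ± 0.33, with edgeR adjusted p values of 0.0163 and 0.0386. With the vehicle UV-A library of each round the differences were 0.52 for MMP1, 0.79 for CYP1B1 and 0.56 for SLC7A11. Some mitotic and mitochondrially encoded mRNAs were lower with 1-SO. CDC20 differed by -1.44 ± 0.24, with an edgeR adjusted p of 0.000424, and MT-ND3 by -1.34 ± 0.29, with an edgeR adjusted p of 0.00627, while MT-CO2 differed by -0.54 ± 0.36, with an edgeR adjusted p of 0.542. Of 13 mitochondrially encoded mRNAs 3 passed as lower, or 7 when adjusted over the list alone, and of 28 G2/M genes 5, or 6 (adjusted p = 0.858 with an estimated correlation for both lists). Over all genes edgeR called 451, 163 with a more positive and 288 with a more negative response to 1-SO, limma-trend on log2(FPKM + 1) called 152 and 173, and DESeq2 called 133. The response to UV-A itself differed between cells with 1-SO and cells with 1-S in 554 genes by edgeR, 215 more positive and 339 more negative with 1-SO, in 221 and 193 by limma-trend and in 112 by DESeq2.

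The responses to the compounds under UV-A were nevertheless related. Across genes, the ratios of 1-SO with UV-A and of 1-S with UV-A, each to the vehicle UV-A library of its own round, correlated at r = 0.613. These comparisons share no library. They had 103 genes in common that were at least 2-fold higher, against 9.2 if unrelated, and 68 that were at least 2-fold lower, against 4.9. 1-SO with UV-A also shared 106 higher and 62 lower genes with 1-S in the dark, at r = 0.596. 1-SO in the dark and 1-S in the dark correlated at r = 0.044.

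Averages over 4 matched pairs were taken of light and of a phosphonium compound of either kind. Over the 4 irradiated and dark pairs the early-response factor EGR1 was higher by a mean log2 of 0.81 ± 0.67 (SD, n = 4 pairs) and FOS by 0.76 ± 0.54. The collagen gene COL4A2 had a mean of -0.80 ± 0.61 and the secreted cystatin CST2 of -0.80 ± 0.46. edgeR called 0 genes for light, with 581 at an unadjusted p under 0.05, DESeq2 0 with 612 and limma-trend 0 with 570. Adjusted over the list alone, 7 of 18 extracellular matrix genes fell, with an adjusted p = 0.497 with an estimated correlation. Ratios had a single sign in 4 of 4 pairs for 1853 genes, 14.6% of those tested, where chance gives 12.5% if the pairs are independent. The vehicle and 1-SO pairs of round 1 correlated at r = 0.536, so the share is not shown to exceed chance.

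Over the 4 pairs of compound and vehicle, GDF15 had a mean log2 ratio of 2.88 ± 2.05 (SD, n = 4 pairs), SNAI1 of 2.54 and DDIT3 of 2.33, while IGFBP4 had -1.76 ± 1.21, the signalling inhibitor SPRY1 -1.47 and E2F1 -1.29. edgeR called 0 genes, with 4335 at an unadjusted p under 0.05, limma-trend 0 with 4329, and DESeq2 2345, 1078 higher and 1267 lower. Without the pair of 1-SO and vehicle in the dark edgeR called 4293. Adjusted over the list alone, 24 of 27 ATF4 genes rose and 1 fell, and 23 of 25 DNA replication genes fell, both with an adjusted p = 0.543 with an estimated correlation. Ratios had a single sign in 4 of 4 pairs for 4727 genes, or 37.2%, beside the 12.5% of chance for independent pairs. The 1-S pairs in the dark and under UV-A correlated at r = 0.902, so the share without agreement between compounds would lie above 12.5%.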

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

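The tests of 1-SO together with UV-A, of chance noise, of plate handling and of a light response by round were chosen after the results were seen, as were the interaction of UV-A with 1-SO and the difference of UV-A between compounds among the results below, while the other tests were written before the values they measure.

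Differences between groups stood out because the difference itself passed a test. UV-A acted differently with 1-SO than with vehicle in 555 genes by edgeR. The compounds differed in 2181 genes in the dark and in 451 under UV-A, each relative to vehicle. The response to UV-A differed between cells with 1-SO and cells with 1-S in 554 genes. Genes listed in the round 2 tables and absent from those of round 1 were outside the comparisons of the report. Of such genes, 543 had an FPKM of at least 1 in at least 2 libraries of round 2. Among these 543, 86 were at least 2-fold higher in 1-S dark than in vehicle dark and 49 were at least 2-fold lower. Between the vehicle libraries of that round 43 were higher with UV-A and 29 lower. UV-A in 1-S, where no gene passed, had 29 higher and 59 lower, and no test was made of these counts.

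The first pattern is the low level of mitochondrially encoded mRNAs after 1-SO with UV-A, whose median log2 ratio was -1.686 after trends with GC content and length were removed and -1.551 before, which argues against composition or length as the cause. The counted reads of nuclear copies of mitochondrial genes did not rise, as the copies' change in RPM was -0.35% of what the mitochondrial genes lost. Only 6 of 175 copies had reads in vehicle UV-A. How counting treated reads shared by a copy and a mitochondrial gene is not given in the sources used here, so this test cannot exclude such sharing. The interaction of UV-A with 1-SO had a median of -1.91 over the 13 mRNAs, which restates the pattern and does not show its cause. 1-S with UV-A, without the oxo group, also had a median of -0.69 with 13 of 13 below 0, yet the difference between the compounds under UV-A was -0.91 on the same scale with 13 of 13 lower for 1-SO, and in the dark the medians were 0.24 for 1-SO and -0.34 for 1-S. The part of the oxo group, which cannot be told apart from round and passage, the single well of this group and a change in poly-A selection all stay open.

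The second pattern is the UV-A response of vehicle cells in round 1, with lower DNA replication and ribosomal protein mRNAs, that round 2 lacked. Chance noise of the vehicle libraries is argued against by the correlation across genes of 0.536 with UV-A in 1-SO, which shares no library with it, and the same correlation was 0.535 after trends with GC content and length were removed. Plate handling stays open, because the labels describe 1 irradiated plate, so light and plate are the same wells. The UV-A responses of vehicle and 1-S cells in round 2 correlated at 0.075, so the prediction of a light response shared within each round was not met there, but no response in round 2 would give this too, and dependence on round or passage is neither shown nor excluded. Handling, passage and light cannot be told apart in these libraries.

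The third pattern is the number of genes with reads, 24644 in 1-S dark and 22495 in its vehicle. Thinned to the same 19.1 M reads, 1-S dark still had 9.97% more genes with reads, 24299 against 22097, which argues against depth. Genomic DNA stays open, because 23 olfactory receptor genes had a read against 17, a ratio of 1.35 with a 95% counting interval of 0.69 to 2.7, while their reads, 94 against 55, had an interval of 1.21 to 2.43 that excludes equal numbers and goes with it. Transcription past gene ends stays open too, since non-coding genes downstream of expressed genes were at least 2-fold higher 1.32 times as often as those upstream, 13.0% of 162 against 9.8% of 51 (one-sided Fisher's exact p = 0.372). 1-S with UV-A went the same way at that depth, with 23114 genes against 21691 in vehicle UV-A. Olfactory receptor reads there were 93 against 67. This pair shares no library with the first. A response to 1-S itself is a biological possibility that no test here separates from genomic DNA or transcription past gene ends.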

How the results depend on the processing

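The alternatives limma-trend on log2(FPKM + 1), TMM over 8 libraries, the read counts of round 1 and every alternative of the edgeR tests of each compound, of UV-A within a compound and of the interactions, and of the UV-A response between compounds, were chosen after the results were seen. Of 152 counts under an alternative, 95 stayed within 1.5 times the main count and 57 did not. Of 930 list medians, 913 moved by less than 0.205 on the log2 scale. That limit came from the difference between the vehicle responses of the rounds, so it holds more than noise. The other 17 moved by more, each with a pseudocount of 0.1 and by at most 0.43. A reversed sign was looked for only among medians of at least 0.5 in size, 55 of 310, and 0 of these reversed. Unless stated, the cause was not tested.

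1-SO in the dark, UV-A in 1-S and the interaction with 1-S had 0 calls in DESeq2 as in edgeR, with 1, 72 and 43 at an unadjusted p under 0.05. In the other compound tests DESeq2 called fewer genes than edgeR, with 471 for 1-SO with UV-A against vehicle UV-A, 685 against vehicle dark, 585 for UV-A in 1-SO, 1569 for 1-S in the dark, 1463 for 1-S with UV-A against vehicle UV-A, 1716 against vehicle dark, 146 for the interaction with 1-SO, 634 and 133 for the difference between compounds in the dark and under UV-A, and 112 for the difference in their UV-A response. For the phosphonium average it called 2345 where edgeR called 0. limma-trend with a pseudocount of 0.1 called 890 for 1-SO with UV-A against vehicle UV-A, 210 for the interaction, 1396 and 196 for the compounds in the dark and under UV-A, and 122 for their UV-A response.

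Results with 0 calls in edgeR gained some. UV-A in vehicle had 23 with no filter on low values, 7 and 3 in limma-trend with pseudocounts of 1 and 0.1, and 2 with TMM over 8 libraries. 1-SO in the dark had 2 and 1 in limma-trend, UV-A in 1-S 3 with no filter and 2 in limma-trend at 0.1, and the interaction with 1-S 3 with no filter and 6 and 4 in limma-trend. With no filter the light average had 279 and the phosphonium average 3008. Leaving out 1 pair gave 0 to 4293 for the phosphonium average, the highest without the 1-SO dark pair, in which no gene passed. Without the replicate block the paired results stayed at 0 genes in edgeR, for UV-A in vehicle, for light and for the phosphonium average, with 16, 58 and 2560 at an unadjusted p under 0.05, so the block changed no call.

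Counts of genes at least 2-fold apart grew with a smaller pseudocount and on read counts, where the genes compared also rose from 12696 to 15386 in round 1 and 16848 in round 2, or 29251 with no filter, so scale and gene set changed together. A pseudocount of 0.1 gave 169 for 1-SO in the dark, 734 and 1398 for 1-SO with UV-A against vehicle UV-A and dark, 1224 for UV-A in 1-SO, 1655 for 1-S dark against vehicle dark, 1912 for 1-S UV-A against vehicle UV-A, 1735 for 1-S UV-A against vehicle dark, and 248 for UV-A in 1-S. In the same order, read counts with TMM gave 444, 1389, 2260, 2071, 3521, 3801, 3554 and 1187. With DESeq2 size factors the 1-S counts were 3523, 3789, 3556 and 1181, and with no filter on counts 6182, 7476, 6621 and 4257. UV-A in 1-S had 71 on FPKM with no filter. For UV-A in vehicle single rounds gave 25 to 76 genes where their mean gave 8. Depth limits genes near the floor of 0.133 to 0.19 CPM.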

Other observations

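The splits of the libraries were tested after the results were seen, and the values of the gene lists below had no test of their own beyond those named.

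Some genes of lipid synthesis, autophagy and antioxidant defence, not described so far, also passed in the tests of the compounds. Of 12 genes of fatty acid synthesis 5 fell after 1-SO with UV-A and 6 after 1-S in the dark, against vehicle under the same light, or 6 in each when adjusted over the list alone (adjusted p = 0.725 and 0.663 with an estimated correlation). FADS2, a fatty acid desaturase, changed by -1.10 on the log2 scale after 1-SO with UV-A. Of 24 genes of cholesterol biosynthesis 6 fell after 1-SO with UV-A, the same when adjusted over the list alone, and after 1-S in the dark 9 fell and 1 rose, or 10 and 1 (adjusted p = 0.725 and 0.663 with an estimated correlation). Of 18 genes of autophagy and mitophagy 5 rose after 1-SO with UV-A and 7 rose and 2 fell after 1-S in the dark, or 6, and 8 with 2, when adjusted over the list alone (adjusted p = 0.725 and 0.663 with an estimated correlation). GABARAPL1, which coats autophagosomes, rose by 1.63 ± 0.20 and by 1.65 in these comparisons, and MAP1LC3B, of the same family, by 1.12 and 1.73. Of 22 antioxidant enzyme genes 7 fell and 1 rose after 1-S in the dark, also when adjusted over the list alone (adjusted p = 0.663 with an estimated correlation), with the mitochondrial peroxiredoxin PRDX3 at -1.25. After 1-SO with UV-A 2 of them rose and 2 fell, or 2 and 3 when adjusted over the list alone (adjusted p = 0.802 with an estimated correlation).

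Some mitochondrial chaperone and epithelial marker genes rose and others fell after 1-S in the dark. Of 16 mitochondrial chaperone and protease genes 4 rose and 3 fell, the same when adjusted over the list alone (adjusted p = 0.918 with an estimated correlation). The chaperonin genes HSPD1 and HSPE1 rose by 1.03 and 1.36 on the log2 scale and HSPA9 by 0.89, while TRAP1, a mitochondrial HSP90, changed by -1.14. Of 11 epithelial and luminal markers 5 rose and 2 fell, also when adjusted over the list alone (adjusted p = 0.663 with an estimated correlation), and ESRP1, a regulator of epithelial splicing, rose from 0.173 to 2.11 FPKM (3.73). Of 10 matrix protease and inhibitor genes 6 fell and 1 rose in both adjustments, PLAT and PLAU changing by -2.17 and -2.22 (adjusted p = 0.663 with an estimated correlation). Adrenomedullin, ADM, of the hypoxia list, rose from 11 to 82.9 FPKM (2.83).

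Other splits of the 8 libraries were tried for the averages over 4 matched pairs. Of 35 splits into 4 and 4, 3 could not be fitted, and 32 of the 32 others gave at least as many genes as the real split, for light and for the phosphonium average alike, since the real value was 0 in each. A count of 0 is reached by any split, so chance cannot be excluded and these splits say nothing further about it. For light the highest other split gave 1779 genes, and it parts irradiated from dark wells in round 1 only. For the phosphonium average the highest other gave 4963 genes, and it parts 1-S from vehicle in round 2 only. These counts point to a structure of the samples that follows those splits, which was not tested further. Among splits that part all 4 pairs the highest other gave 0 for light and 1 for the phosphonium average.

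A smooth trend with gene length over all genes tested did not account for the lower ratios of extracellular matrix genes after UV-A in 1-S. Across genes the log2 ratio of UV-A in 1-S had a Spearman correlation of -0.186 with length. The matrix genes had a median length of 8932 bases against 4694 over all genes tested. Removing the trends with length and GC content left the median of the list at -0.39, from -0.41. An effect of length that such a trend misses, as in the longest genes alone, was not tested.

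The level of ASNS, a gene chosen after its values were seen, differed more between rounds than between the libraries of a round, at 41.5 FPKM in the vehicle dark library of round 1 and 0.219 in that of round 2. NUPR1, noticed in the same way, stood at 4.13 and 0.437. The gene models of the rounds differ, so these levels are given as values only.

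The authors' deposited tables for clustering held 176 genes for round 1 and 714 for round 2, with 73 in both.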
